A study of Homo sapiens with 10 samples.

How the data were processed

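RNA of MCF-7 cells, an established human breast cancer line, was sequenced in 10 libraries, 2 in each of 5 groups: control cells with a non-targeting guide, control cells with 300 nM GDC-9545, ESR1-edited cells, FOXA1-edited cells and FOXA1-edited cells with 300 nM GDC-9545, all taken at 4 days. The deposited table holds raw counts per Ensembl gene, 58302 genes, with whole numbers and 1 column per library, not normalized, as tested on the values. The submitters' processing notes name the aligner GSNAP and the genome build GRCh38. The counting tool, its annotation release, the software versions and whether reads were counted by strand are not given in the sources used here. The labels name the TruSeq RNA v2 and the TruSeq Stranded Total RNA kits without saying which library was made with which, so a kit could not be set as a term. Total counts per library were 28754114 and 28879295 for control, 25942709 and 29573403 for drug-treated control, 22033284 and 20283645 for ESR1-edited, 35313413 and 18252074 for FOXA1-edited, and 21111770 and 19343149 for drug-treated FOXA1-edited cells. Bounds on folds from a group at 0 counts use a floor of 3 counts over the group and cover counting error alone, since reads without molecular identifiers are not independent molecules.

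Gene symbols, positions and transcript GC content came from GENCODE release 29 on GRCh38, which holds 58039 of the IDs, and 41836 IDs had a symbol in the gene name table. Counts were fitted with edgeR 4.0.16 (R 4.3.3) in 1 model of all 10 libraries with 1 mean per group and 5 residual degrees of freedom, after TMM normalization and filterByExpr by group, which left 16833 genes. The quasi-likelihood F test gave p-values, two-sided and adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The SE of an edgeR log2 change is the size of the change divided by the square root of F. Comparisons were the drug in control cells, ESR1 editing, FOXA1 editing, FOXA1 editing under the drug, the drug in FOXA1-edited cells, the interaction of drug and FOXA1 editing, the drug against ESR1 editing, and FOXA1 against ESR1 editing. CPM values are TMM-normalized, with the SD over 2 libraries. Camera of limma 3.58.1 compared each of 17 fixed gene lists with all other genes at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison, for lists of at least 5 genes. The filter can keep a gene expressed in only 1 group, so list members may have entered through the groups where they are high. It kept 12 of 20 inflammatory, 17 of 22 basal, 15 of 19 mesenchymal, 6 of 14 other cell type and 13 of 30 histone genes. The lists were estrogen-induced, estrogen-repressed, luminal epithelial, basal and myoepithelial, mesenchymal, mitosis, DNA replication and E2F, interferon-stimulated, p53 target, cholesterol synthesis, unfolded protein and stress response, inflammatory and NF-kB target, growth factor receptor and ligand, nuclear receptor with FOXA and coregulator, other cell type, mitochondrially encoded and replication-dependent histone genes. Named genes followed a rule: ESR1 and FOXA1 always, the 7 genes with the largest increase and the 7 with the largest decrease among called genes with a symbol, at least 2 CPM in a compared group and no overlap between replicates, up to 4 members of each list with the smallest p, and TFF1, GREB1 and PGR. The design, tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

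Each library's trend on GC content was removed, as an alternative, by fitting a spline with 5 degrees of freedom to its deviation from the gene means over 10255 genes with a mean log2 CPM above 2, using the longest transcript of each gene, and adding the trend to the edgeR offsets. GC content was known for 16790 of the tested genes, or 99.7%. This correction, its combination with transcript length, with the replicate number as a block or with a library left out, the naming rule applied to it, and limma-voom with sample quality weights were chosen after the data were seen. The alternatives chosen in advance were DESeq2 1.42.0 as the tool or for its size factors, limma-voom, no filter, a filter of at least 1 CPM in at least 2 libraries, the compared groups alone, the replicate block, an adjusted p under 0.01, a log2 change of at least 1, an estimated inter-gene correlation, fry, and each library left out. Overlaps between comparisons were set against lists drawn independently and against 10 simulations of unchanged groups sharing simulated control libraries, with counts drawn independently for each gene. The pipeline was tested on simulated data with changes of log2 1, 2 and 3 in 67, 67 and 66 of 16833 genes: for the drug in control cells, counts as deposited recovered 0% of changes of log2 1, 11.9% of log2 2 and 57.6% of log2 3, and the GC-corrected fit 14.9%, 73.1% and 93.9%, with 0 and 3 false calls among 16633 unchanged genes. For FOXA1 editing the recovered shares were 0%, 5.97% and 57.6%, and 13.4%, 74.6% and 95.5%, with 0 and 3 false calls, and DESeq2 made 142 false calls there. The simulated counts carried the GC trends and dispersions of the GC-corrected fit. Changes were placed only in genes with a mean log2 CPM above 2. That setting favored the GC-corrected fit in advance, so these shares do not test the correction against the other fits. Groups of 2 libraries allow no test of other splits of the samples. Figures were drawn with Python 3.11.15.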

Results

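RNA was sequenced from MCF-7, an estrogen receptor-positive human breast cancer cell line, after Cas9 ribonucleoprotein editing and drug treatment. Cells received a non-targeting guide (control cells), a guide against ESR1, which encodes estrogen receptor alpha, or a guide against FOXA1, a pioneer transcription factor of luminal breast cells. Control and FOXA1-edited cells were also grown for 4 days in 300 nM GDC-9545 (giredestrant), an oral antagonist and degrader of estrogen receptor alpha. The 10 libraries formed 5 groups of 2, named below as control, drug-treated control, ESR1-edited, FOXA1-edited and drug-treated FOXA1-edited cells. Total counts per library ran from 18252074 in FOXA1-edited replicate 2 to 35313413 in FOXA1-edited replicate 1. The labels call the libraries of a group duplicates without naming separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicate libraries correlated across genes at r = 0.984 for drug-treated control, 0.976 for ESR1-edited, 0.959 for control, 0.952 for drug-treated FOXA1-edited and 0.81 for FOXA1-edited cells (log2 CPM, genes not being independent replicates). Read counts followed transcript GC content differently in each library: relative to each gene's mean, genes with a transcript GC content above 54.2% stood at a median log2 of 1.75 in FOXA1-edited replicate 2 and -1 in control replicate 2. Results are given for the counts as deposited, by the design fixed in advance. Beside them stand results of a fit with each library's GC trend removed, a correction chosen after the data were seen. The median log2 change of all genes tested was 0.105 with FOXA1 edited, -0.117 for the drug in FOXA1-edited cells, -0.127 for the interaction and 0.116 for FOXA1-edited against ESR1-edited cells. The GC-corrected medians were 0.0614, -0.0104, -0.022 and 0.0585, and list tests compare members with the other genes.

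**Figure D1:**
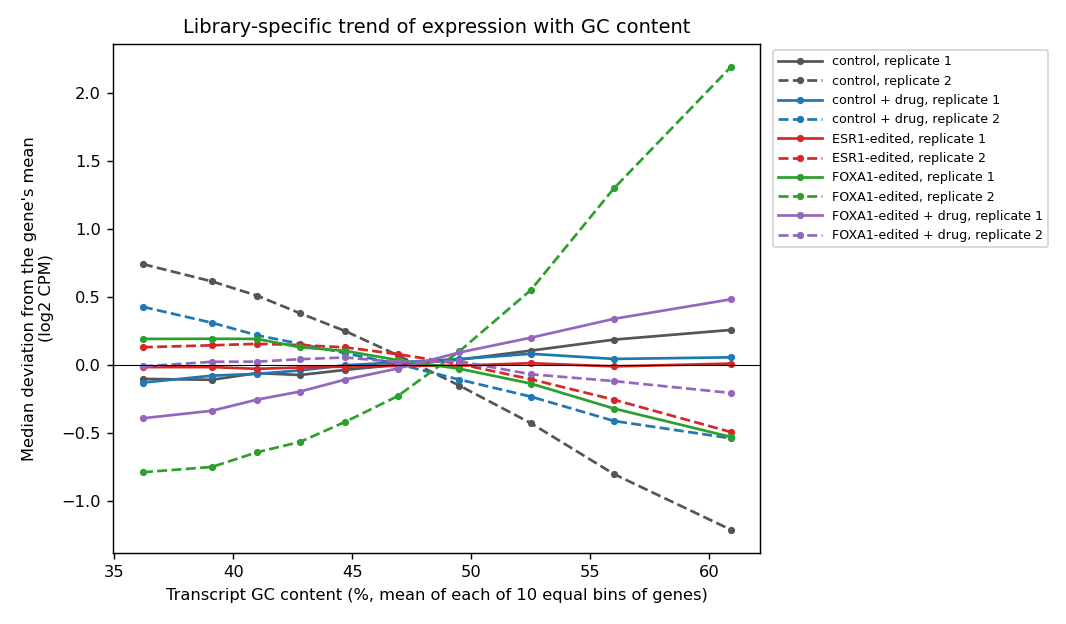
Median deviation of each library from the gene means (log2 CPM, y axis) in 10 equal bins of genes by transcript GC content (percent, x axis), with 1 line per library, colored by group, solid for replicate 1 and dashed for replicate 2. FOXA1-edited replicate 2 climbs toward GC-rich genes, and control replicate 2 falls.

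ESR1 (chromosome 6, 151656691 to 152129619, GRCh38, GENCODE release 29) measured 497 ± 118 CPM in control cells (mean ± SD, n = 2), 296 ± 40.3 in drug-treated control, 131 ± 11.9 in ESR1-edited, 88.7 ± 18.4 in FOXA1-edited and 80.8 ± 25.5 in drug-treated FOXA1-edited cells. FOXA1 (chromosome 14, 37589984 to 37596059) measured 448 ± 179, 473 ± 114, 428 ± 13.7, 268 ± 75.2 and 233 ± 44.2 CPM in the same order. ESR1 RNA fell with FOXA1 edited, with a log2 fold change of -2.48 (SE 0.33, edgeR adjusted p = 0.0248) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the source of every edgeR adjusted p here. With ESR1 itself edited, the ESR1 change was -1.92 (SE 0.33, edgeR adjusted p = 0.336), past the threshold once GC trends were removed, at -1.90 (SE 0.22, GC-corrected edgeR adjusted p = 0.0168). The FOXA1 transcript in FOXA1-edited against control cells was at -0.74 (SE 0.36, edgeR adjusted p = 0.297) and -1.05 (SE 0.47, GC-corrected edgeR adjusted p = 0.247), neither past the threshold. The FOXA1-edited libraries held 321 and 214 CPM against 321 and 574 in controls. Gene-level RNA counts do not measure the edit or the protein.

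**Figure D2:**
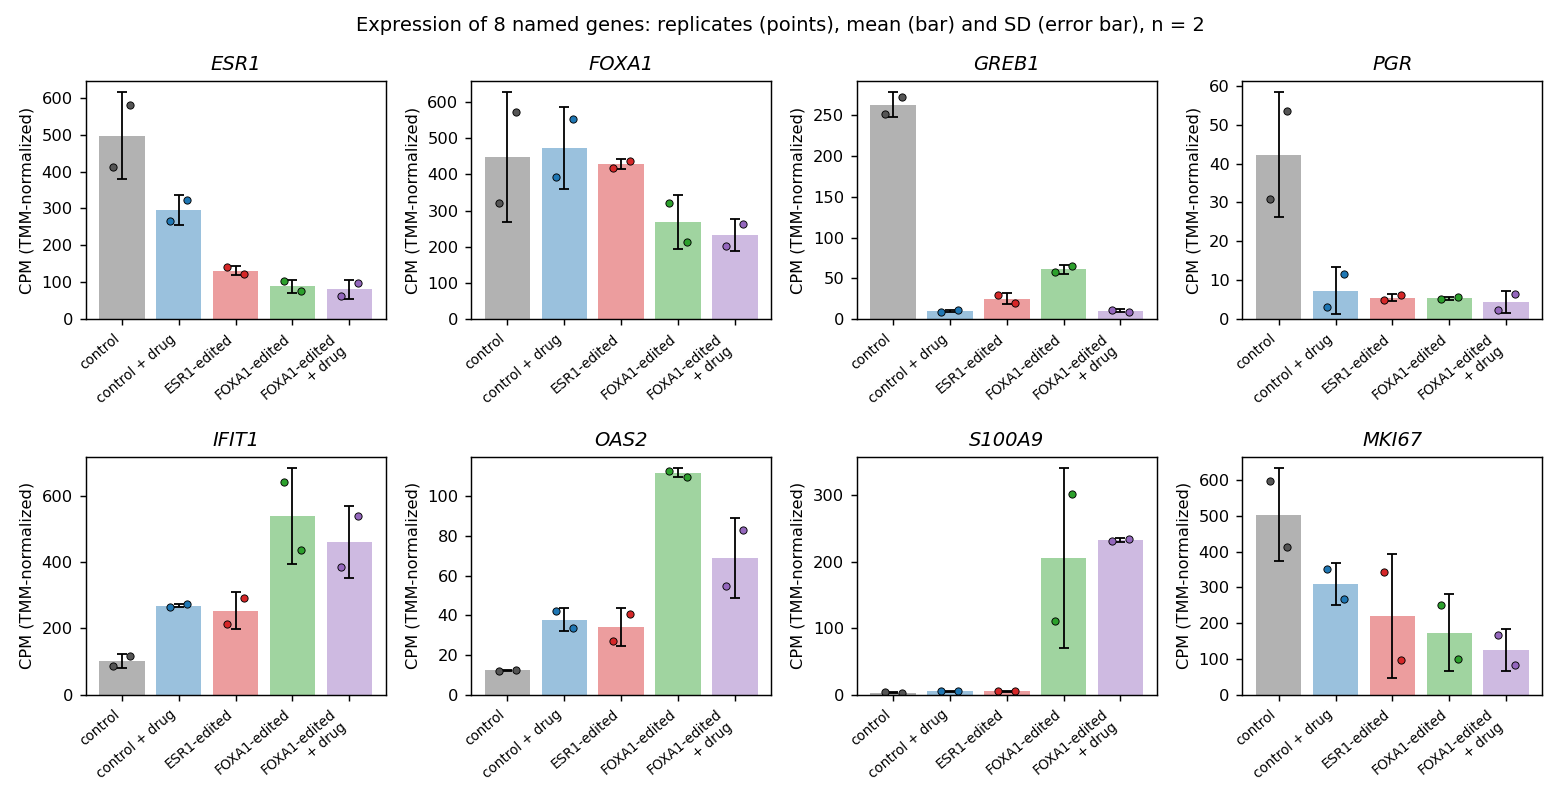
Expression of 8 genes (y axes, CPM with TMM normalization, linear from 0) in the 5 groups (x axes), with points for the 2 replicates, bars for the mean and error bars for the SD. GREB1 stands at 263 CPM in control cells and 9.84 in drug-treated control cells, and S100A9 at 3.26 CPM in control and 206 in FOXA1-edited cells.

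GDC-9545 in control cells asked which transcripts follow estrogen receptor blockade. GREB1, an estrogen receptor target and cofactor, fell from 263 ± 15.1 to 9.84 ± 1.1 CPM (n = 2 each), a log2 fold change of -4.74 (SE 0.33, edgeR adjusted p = 0.00415). GFRA1, a co-receptor for glial cell line-derived ligands, fell from 1120 ± 80.7 to 139 ± 3.32 CPM, at -3.00 (SE 0.26, edgeR adjusted p = 0.0119). These were the 2 genes called among 16833 tested. In the GC-corrected fit, 76 genes were called, 39 higher and 37 lower, including both. The largest increase by the naming rule in that fit was in APOD, which encodes apolipoprotein D, from 34.8 ± 13.3 to 232 ± 40.5 CPM at 2.70 (SE 0.33, GC-corrected edgeR adjusted p = 0.0114). The others were GABBR2 at 2.70, BCAS1 at 2.40, XAF1 at 2.21, CRISP3 at 2.17, SELL (L-selectin) at 2.04 and ITGB6 (integrin beta 6) at 1.88. The largest decreases besides GREB1 were IGSF1 at -5.19, ARHGAP36 at -4.54, CDH26, a cadherin, at -4.41, the hedgehog ligand gene SHH at -3.98, the calcitonin receptor gene CALCR at -3.83 and AGR3 at -3.56. The progesterone receptor gene PGR stood at 42.3 ± 16 and 7.34 ± 5.95 CPM (log2 -2.52, edgeR adjusted p = 0.953). The trefoil factor gene TFF1 stood at 18.7 ± 16.8 and 3.29 ± 1.18 CPM (log2 -2.50, edgeR adjusted p = 1).

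Of 38 estrogen-induced genes, 1 fell over all genes tested and 13 fell adjusted over the list alone, against 8 and 23 with GC trends removed. Among them were CXCL12 at -2.47 and CA12, a carbonic anhydrase, at -1.81 in the GC-corrected fit. The list's median log2 change was -1.25 with 1 of 38 above 0 (camera adjusted p = 1.42e-49, and adjusted p = 0.0034 with an estimated correlation). The 13 estrogen-repressed genes had a median of 1.06 (camera adjusted p = 7.69e-19, and adjusted p = 0.00182 with an estimated correlation). Of these, 0 were called over all genes and 5 rose adjusted over the list alone, and 7 rose over all genes with GC trends removed, BCAS1 among them. The 21 mitosis genes were lower as a list, at a median of -0.85 (camera adjusted p = 5.98e-19, and adjusted p = 0.0035 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. With GC trends removed, 16 of them fell adjusted over the list alone and 0 over all genes. The 28 DNA replication and E2F genes were lower at -0.96 (camera adjusted p = 2.34e-23, and adjusted p = 0.00153 with an estimated correlation). Adjusted over the list alone 9 of them fell, over all genes 0, and with GC trends removed 20 fell over the list alone and MCM4 and RFC3 over all genes. Interferon-stimulated genes rose as a list, median 0.95 with 25 of 25 above 0 (camera adjusted p = 1.37e-24, and adjusted p = 0.00383 with an estimated correlation). Over all genes 0 were called, adjusted over the list alone 6, and over all genes with GC trends removed 5. IFIT1, an interferon-induced antiviral gene, was at 102 ± 21.3 and 269 ± 5.6 CPM, 1.51 (SE 0.17, GC-corrected edgeR adjusted p = 0.00757). The mesenchymal list also stood higher, median 0.81 (camera adjusted p = 1.89e-05, and adjusted p = 0.0137 with an estimated correlation), with 0 of 15 called over all genes or adjusted over the list alone. Of 19 nuclear receptor, FOXA and coregulator genes, a list whose direction the design read from no test, GREB1 fell and 18 were not called. Adjusted over that list alone 1 fell, and its median was 0.05 against a mean of -0.40 (camera adjusted p = 0.00387, and adjusted p = 0.0484 with an estimated correlation, or 0.171 with GC trends removed). The inflammatory and NF-kB list (median 0.54) and the mitochondrially encoded genes (median 0.43) were at camera adjusted p = 0.00397 and 4.42e-05. They were at adjusted p = 0.135 and adjusted p = 0.172 with an estimated correlation. The luminal list at -0.02 (camera adjusted p = 0.0683), basal list at 0.50 (0.151), p53 targets at 0.11 (0.0857) and cholesterol synthesis genes at -0.30 (0.0845) did not pass. GC-corrected, the luminal list and p53 targets were at -0.06 and 0.15 (camera adjusted p = 0.0298 and 0.0298, but adjusted p = 0.114 and 0.114 with an estimated correlation). Nor did the unfolded protein and stress response list at 0.14 (camera adjusted p = 0.38), growth factor receptors and ligands at 0.27 (0.455), other cell type markers at 0.40 (0.189) and histones at 0.34 (0.209). The count of 2 genes became 0 without either drug-treated control library and 1 without either library of the control, ESR1-edited or drug-treated FOXA1-edited cells. It became 16 without FOXA1-edited replicate 1 and 18 without FOXA1-edited replicate 2. The GC-corrected count of 76 became 1 without either drug-treated control library, 11 and 9 without control replicates 1 and 2, and 28 without either ESR1-edited library. It became 39 and 34 without drug-treated FOXA1-edited replicates 1 and 2, and 277 and 318 without FOXA1-edited replicates 1 and 2.

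Editing ESR1 asked which transcripts follow loss of the receptor gene. GREB1 was the 1 gene called, falling from 263 ± 15.1 to 24.9 ± 6.5 CPM (n = 2 each), a log2 fold change of -3.40 (SE 0.31, edgeR adjusted p = 0.0383). With the GC trends removed, 49 genes were called, 29 higher and 20 lower. By the naming rule in that fit the largest increase was in APOD, from 34.8 ± 13.3 to 246 ± 51.5 CPM at 2.78 (SE 0.33, GC-corrected edgeR adjusted p = 0.0168). GABBR2 rose at 2.29, SELL at 2.21, CRISP3 at 2.11, BCAS1 at 1.97, ITGB6 at 1.73 and VTCN1 at 1.72. The largest decreases besides GREB1 were IGSF1 at -3.47, SHH at -3.42, CDH26 at -2.81, the chemokine gene CXCL12 at -2.22 and GFRA1 at -2.19. The neuropeptide Y receptor gene NPY1R fell at -2.62 (SE 0.20, GC-corrected edgeR adjusted p = 0.00443). PGR stood at 5.44 ± 0.901 CPM (log2 -2.96 against control, edgeR adjusted p = 1) and TFF1 at 5.81 ± 1.1 CPM (log2 -1.68, edgeR adjusted p = 1). Estrogen-induced genes had a median of -0.999 (camera adjusted p = 7.83e-39, and adjusted p = 0.00494 with an estimated correlation). Of 38, 1 fell over all genes, 13 adjusted over the list alone and 6 over all genes with GC trends removed. Estrogen-repressed genes had a median of 0.81 (camera adjusted p = 1.71e-13, and adjusted p = 0.00417 with an estimated correlation). Of 13, 0 were called over all genes, 2 adjusted over the list alone and 4 over all genes with GC trends removed. Mitosis genes were lower as a list at -0.72 (camera adjusted p = 2.06e-13, and adjusted p = 0.00683 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone, and 11 of 21 over the list alone with GC trends removed. DNA replication and E2F genes were lower at -0.71 (camera adjusted p = 2.12e-14, and adjusted p = 0.00417 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone. After GC correction these counts were 1 and 8. Interferon-stimulated genes were higher at a median of 1.04 (camera adjusted p = 1.55e-27, and adjusted p = 0.00494 with an estimated correlation). Of 25, 0 were called over all genes, 9 adjusted over the list alone, and IFIT1, XAF1 and IFI44L over all genes with GC trends removed. Mesenchymal genes had a median of 0.67 (camera adjusted p = 6.66e-05, and adjusted p = 0.0179 with an estimated correlation) with 0 of 15 called. The inflammatory list (0.60), the basal list (0.34), p53 targets (0.08) and the 6 markers of other cell types (1.18) were at camera adjusted p = 0.00364, 0.0443, 0.0375 and 0.0273. These became adjusted p = 0.108, 0.12, 0.108 and 0.187 with an estimated correlation. Of 19 nuclear receptor, FOXA and coregulator genes, GREB1 fell, 2 fell adjusted over the list alone, and 5 were above 0. That list was at a median of -0.21 (camera adjusted p = 0.000215, and adjusted p = 0.0195 with an estimated correlation, or 0.0662 with GC trends removed). The luminal list was at -0.06 (camera adjusted p = 0.0665), or -0.12 with GC trends removed (camera adjusted p = 0.0214, adjusted p = 0.0766 with an estimated correlation). The count of 1 gene became 0 without any single library of the control, drug-treated control, ESR1-edited or drug-treated FOXA1-edited groups, 2 without FOXA1-edited replicate 1 and 7 without FOXA1-edited replicate 2. The GC-corrected count of 49 became 0 without either ESR1-edited library or control replicate 2, 2 without control replicate 1, and 6 and 9 without drug-treated control replicates 1 and 2. It became 24 without either drug-treated FOXA1-edited library, and 150 and 175 without FOXA1-edited replicates 1 and 2.

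Editing FOXA1 in untreated cells asked which transcripts follow loss of the pioneer factor. S100A8, a calprotectin subunit gene, rose from 0.654 ± 0.154 to 71.1 ± 2.19 CPM (n = 2 each), a log2 fold change of 6.75 (SE 0.42, edgeR adjusted p = 0.00161). The other subunit gene, S100A9, rose from 3.26 ± 0.585 to 206 ± 135 CPM at 5.98 (SE 0.52, edgeR adjusted p = 0.006). EPGN, which encodes the EGFR ligand epigen, had 0 counts in the control libraries and 258 in the FOXA1-edited libraries, at least 85.9-fold higher with a floor of 3 counts over the group. Other large increases were the kallikrein protease gene KLK6 at 6.17 (SE 1.02, edgeR adjusted p = 0.0406), GRAMD1B at 6.08 and OLFML3 at 5.83. NEURL3 went from 2 counts to 162. PMP22, the peripheral myelin protein gene, fell from 83.6 ± 19.7 to 2.35 ± 2.09 CPM at -5.19 (SE 0.65, edgeR adjusted p = 0.0227). CSTA, which encodes the protease inhibitor cystatin A, fell from 35.2 ± 10.4 to 1.02 ± 0.382 CPM at -5.07 (SE 0.47, edgeR adjusted p = 0.00709). LDLRAD4 at -4.88, IGSF1 at -4.34, PLEKHH2 at -4.31 and SHH at -3.82 also fell. UGT2B15, a steroid glucuronidation gene whose close paralogs can share reads, went from 120 counts to 0, at least 40.1-fold lower. In all, 119 genes were called, 78 higher and 41 lower, against 841 (468 and 373) with GC trends removed, 114 of them in both. The test pools the spread of all groups, while the FOXA1-edited libraries differed more than any other replicate pair (r = 0.81 across genes). Its p-values may therefore understate the spread of this group. With the compared groups alone, which leaves fewer residual degrees of freedom, edgeR called 0 genes, and limma-voom with sample quality weights called 5. Within FOXA1-edited cells, KLK6 measured 45.8 and 390 CPM, OLFML3 16.7 and 77 and TFF1 1.07 and 62.1 in the 2 libraries. TFF1 was at log2 0.76 with both libraries and -4.14 without FOXA1-edited replicate 2, neither past the threshold (edgeR adjusted p = 0.746 and 0.0557). PGR was at -2.99 (SE 0.73, edgeR adjusted p = 0.124).

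Interferon-stimulated genes rose with FOXA1 edited: 12 of 25 over all genes, 24 adjusted over the list alone and 21 over all genes with GC trends removed. Their median log2 change was 2.82 (camera adjusted p = 1.91e-34, and adjusted p = 0.00691 with an estimated correlation). OAS2, an antiviral oligoadenylate synthetase gene, went from 12.3 ± 0.287 to 112 ± 2.28 CPM at 3.18 (SE 0.35, edgeR adjusted p = 0.0176), IFIT3 was at 2.93 and IFIT2 at 2.50. Inflammatory and NF-kB target genes had a median of 2.86 (camera adjusted p = 1.71e-11, and adjusted p = 0.0116 with an estimated correlation), with 1 of 12 called, 11 adjusted over the list alone and 7 with GC trends removed. The filter had kept 12 of that list's 20 genes, some perhaps only through FOXA1-edited libraries where they are high, which would raise the median. The cytokine gene IL6 rose from 1.03 ± 0.38 to 16.2 ± 1.67 CPM at 3.97 (SE 0.51, edgeR adjusted p = 0.0227), and the chemokine gene CXCL8 was at 5.68 (SE 0.82, GC-corrected edgeR adjusted p = 0.00588). Basal and myoepithelial genes were higher, median 1.54 (camera adjusted p = 4.26e-08, and adjusted p = 0.0116 with an estimated correlation). ANXA1 (annexin A1) at 2.58 (SE 0.28, edgeR adjusted p = 0.0167) and the laminin gene LAMC2 at 2.74 were the 2 of 17 called, with 7 adjusted over the list alone and 6 with GC trends removed. Of 38 estrogen-induced genes, GREB1 (-2.11), ELOVL2 (-2.70), MYB (-2.28) and XBP1 (-1.53) fell. Adjusted over the list alone 14 fell and 4 rose, and 13 fell over all genes with GC trends removed. That list's median was -0.60 (camera adjusted p = 8.66e-06, and adjusted p = 0.144 with an estimated correlation), and -1.07 with GC trends removed (camera adjusted p = 1.12e-12, adjusted p = 0.028 with an estimated correlation). Mitosis genes were lower, median -1.21 (camera adjusted p = 2.91e-11, and adjusted p = 0.0116 with an estimated correlation). Of 21, 0 were called, 11 adjusted over the list alone and 11 over all genes with GC trends removed. DNA replication and E2F genes were lower at -0.73 (camera adjusted p = 8.66e-06, and adjusted p = 0.0116 with an estimated correlation). The replication helicase subunit gene GINS1 at -1.86 (SE 0.28, edgeR adjusted p = 0.0281) was the 1 of 28 called, with 8 adjusted over the list alone and 7 with GC trends removed. The stress response list was higher at 0.98 (camera adjusted p = 0.000865, and adjusted p = 0.047 with an estimated correlation), with the stress-induced transcription factor gene ATF3 at 2.26 the 1 of 16 called and 3 adjusted over the list alone. Mesenchymal genes were higher as a list at 1.5 (camera adjusted p = 0.00286, and adjusted p = 0.047 with an estimated correlation), with 0 called and 2 adjusted over the list alone. Of 15 members 14 were above 0, while the vimentin gene VIM went from 28 counts in the control libraries to 2. The p53 targets were higher at 0.71 (camera adjusted p = 0.00256, and adjusted p = 0.047 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. In the GC-corrected fit those 3 lists had medians of 0.57, 1.10 and 0.43, at adjusted p = 0.0952, 0.0558 and 0.028 with an estimated correlation. Over all genes 4, 2 and 4 of their members then rose, and 4, 4 and 5 adjusted over each list alone, where 1 mesenchymal gene fell. Mitochondrially encoded genes stood at a median of -0.59 (camera adjusted p = 0.000103, adjusted p = 0.187 with an estimated correlation). The luminal list did not pass (median 0.20 with camera direction lower, adjusted p = 0.422 with an estimated correlation), although its members ESR1 and XBP1 fell. In the GC-corrected fit it was lower at -0.13 (camera adjusted p = 0.00101, adjusted p = 0.0411 with an estimated correlation), with AGR2 at -2.46 and AGR3 at -4.12. The estrogen-repressed list at 0.43 (camera adjusted p = 0.257), cholesterol synthesis at -0.20 with a mean of 0.36 (0.678) and growth factor list at 0.31 (0.789) did not pass. Within them BLNK rose from 2.36 ± 0.369 to 21.7 ± 2.13 CPM and ERBB4, a receptor tyrosine kinase gene, fell at -3.77 (SE 0.56, edgeR adjusted p = 0.0286). Other cell type markers at 0.76 (camera adjusted p = 0.903) and histones at -0.02 (0.903) did not pass either. The count of 119 became 429 without FOXA1-edited replicate 2 and 4470 without replicate 1, where the remaining library is assumed to vary like the other groups. It became 3 and 2 without control replicates 1 and 2, 8 and 7 without drug-treated control 1 and 2, 10 and 7 without ESR1-edited 1 and 2, and 7 without either drug-treated FOXA1-edited library. With GC correction, 841 became 233 and 165 without control replicates 1 and 2, 460 and 464 without drug-treated control 1 and 2, 513 and 515 without ESR1-edited 1 and 2, and 2480 without FOXA1-edited replicate 1.

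**Figure D3:**
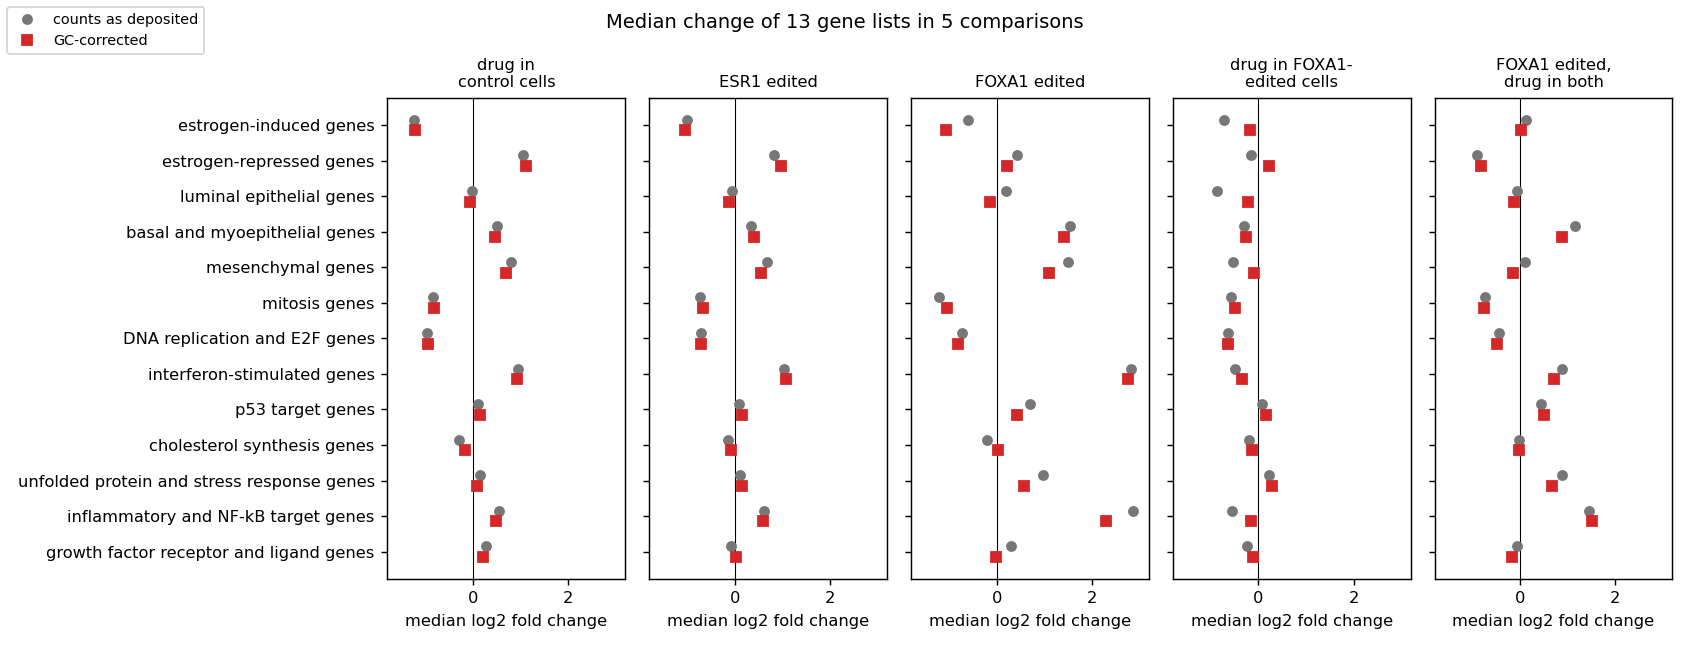
Median log2 fold change (x axis) of 13 gene lists (y axis) in 5 comparisons, as circles for counts as deposited and squares for the GC-corrected fit. Interferon-stimulated genes stand at 0.95 with the drug in control cells, 1.04 with ESR1 edited and 2.82 with FOXA1 edited, for counts as deposited.

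FOXA1 editing was also compared under the drug, with GDC-9545 in both arms. S100A8 rose from 1.34 ± 0.276 to 135 ± 27.3 CPM (n = 2 each), at 6.65 (SE 0.42, edgeR adjusted p = 0.00158). S100A9 rose from 5 ± 0.118 to 233 ± 2.87 CPM at 5.54 (SE 0.51, edgeR adjusted p = 0.00612). CLMP, an adhesion molecule gene, at 6.30 (SE 0.58, edgeR adjusted p = 0.00612), OLFML3 at 5.90, GRAMD1B at 5.51, the epidermal caspase gene CASP14 at 4.84 and UGT1A7 at 6.13, which shares exons with its UGT1A neighbors, rose as well. ERBB4 fell from 36.6 ± 6.18 to 0.757 ± 0.0533 CPM at -5.58 (SE 0.62, edgeR adjusted p = 0.0144), and CSTA from 77.1 ± 5.04 to 2.41 ± 0.513 CPM. PMP22 (-5.57), LDLRAD4 (-6.29), the glycine receptor gene GLRA3 (-3.91), PPP1R3C (-3.76) and the aldehyde oxidase gene AOX1 (-3.64) fell too. In all 49 genes were called, 28 higher and 21 lower, and 507 (255 and 252) with GC trends removed, including all 49. GREB1 measured 9.84 ± 1.1 and 10.2 ± 1.95 CPM (log2 0.05, SE 0.29, edgeR adjusted p = 0.982). PGR was at -0.76 (SE 0.69, edgeR adjusted p = 0.888) and TFF1 at 0.07 (SE 1.32, edgeR adjusted p = 0.996). Inflammatory and NF-kB target genes had a median of 1.45 (camera adjusted p = 3.49e-08, and adjusted p = 0.0224 with an estimated correlation), with IL6 at 3.68 the 1 of 12 called, 6 adjusted over the list alone and 4 over all genes with GC trends removed. Basal and myoepithelial genes were higher at 1.16 (camera adjusted p = 2.92e-08, and adjusted p = 0.0224 with an estimated correlation). CD44, a cell-surface hyaluronan receptor gene, at 2.71 (SE 0.24, edgeR adjusted p = 0.00612) and ANXA1 at 1.87 were the 2 of 17 called, with 3 adjusted over the list alone and 4 over all genes with GC trends removed. Interferon-stimulated genes had a median of 0.88 (camera adjusted p = 3.75e-09, and adjusted p = 0.0253 with an estimated correlation), with IFIT2 at 2.02 the 1 of 25 called and 4 adjusted over the list alone. In the GC-corrected fit that list was at 0.72 with 7 called higher (camera adjusted p = 4.29e-13, but adjusted p = 0.0528 with an estimated correlation). The stress response list was higher at 0.88 (camera adjusted p = 7.29e-07, and adjusted p = 0.0224 with an estimated correlation), with 0 of 16 called and 4 adjusted over the list alone. The p53 targets were higher at 0.45 (camera adjusted p = 0.00239, and adjusted p = 0.0344 with an estimated correlation), with 0 of 23 called over all genes or adjusted over the list alone. The GC-corrected fit called 4 stress response genes and 2 p53 targets higher over all genes, and 5 and 6 adjusted over each list alone. Mitosis genes were lower as a list at -0.73 (camera adjusted p = 3.49e-08, and adjusted p = 0.0224 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. DNA replication and E2F genes were lower at -0.45 (camera adjusted p = 0.000318, and adjusted p = 0.0224 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. With GC trends removed, 4 mitosis genes fell over all genes and 11 of 21 over the list alone, and 0 and 8 replication genes. Estrogen-repressed genes were lower at -0.90 (camera adjusted p = 0.000112, and adjusted p = 0.0224 with an estimated correlation), with BCAS1 at -2.57 the 1 of 13 called. Adjusted over that list alone, 4 fell and 1 rose, and over all genes with GC trends removed 6 fell and 1 rose. Estrogen-induced genes had a median of 0.12 (camera adjusted p = 0.348), with 0 of 38 called over all genes and, adjusted over the list alone, 3 higher and 2 lower, or 2 higher and 2 lower over all genes with GC trends removed. The luminal list was at -0.07 (camera adjusted p = 0.00405, adjusted p = 0.131 with an estimated correlation). GC-corrected, it was lower at -0.13 (camera adjusted p = 0.000181, adjusted p = 0.0339 with an estimated correlation), with ESR1, AGR3, AGR2, SPDEF and ERBB3 the 5 of 22 that fell over all genes. Mitochondrially encoded genes were at -0.70 (camera adjusted p = 7.22e-07, adjusted p = 0.122 with an estimated correlation), with 0 of 13 called, or 7 adjusted over the list alone with GC trends removed. The count of 49 became 0 without either drug-treated control library, 2 and 1 without drug-treated FOXA1-edited replicates 1 and 2, and 9 without either ESR1-edited library. It became 32 without either control library, 271 without FOXA1-edited replicate 1 and 340 without replicate 2. With GC correction, 507 became 113 and 97 without drug-treated control replicates 1 and 2, 203 and 143 without drug-treated FOXA1-edited 1 and 2, 315 and 309 without ESR1-edited 1 and 2, and 1035 and 1110 without FOXA1-edited 1 and 2.

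In FOXA1-edited cells, GDC-9545 left GREB1 at 10.2 ± 1.95 CPM against 61 ± 5.28 without the drug (n = 2 each; log2 -2.58, SE 0.30, edgeR adjusted p = 0.276). PGR measured 5.33 ± 0.38 and 4.33 ± 2.81 CPM without and with the drug, CXCL12 37.6 ± 3.84 and 45.7 ± 3.59, and ESR1 88.7 ± 18.4 and 80.8 ± 25.5. By edgeR 0 genes were called, with 810 at an unadjusted p under 0.05, while DESeq2 called 25 and limma-voom 0. The GC-corrected edgeR fit called 0, with 1142 at an unadjusted p under 0.05. Without FOXA1-edited replicate 2 edgeR called 109 genes, 11 higher and 98 lower, and without replicate 1 it called 588. GREB1 was then at log2 -2.49 without replicate 2 (edgeR adjusted p = 0.00819). DNA replication and E2F genes were lower as a list, median -0.65 with 1 of 28 above 0 (camera adjusted p = 1.1e-08, and adjusted p = 0.0159 with an estimated correlation), and 0 were called over all genes or adjusted over the list alone, against 0 and 10 with GC trends removed. Estrogen-induced genes (-0.72), mitosis genes (-0.57), interferon-stimulated genes (-0.48) and luminal genes (-0.86) were at camera adjusted p = 5.81e-05, 0.000125, 0.000125 and 0.0106. They were at adjusted p = 0.271, 0.181, 0.225 and 0.271 with an estimated correlation, and 1, 0, 0 and 1 members fell adjusted over each list alone. GC-corrected medians of these lists were -0.18, -0.49, -0.35 and -0.22, at camera adjusted p = 0.000402, 2.84e-10, 2.24e-08 and 0.0216. The mitosis list then passed at adjusted p = 0.0483 with an estimated correlation, and the others were at adjusted p = 0.216, 0.216 and 0.197. Adjusted over each list alone 4, 0, 0 and 1 members then fell. Mitochondrially encoded genes were higher at 0.33 (camera adjusted p = 0.000352, but adjusted p = 0.305 with an estimated correlation). The luminal list turned to higher without FOXA1-edited replicate 2, at camera adjusted p = 0.785.

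The difference between the drug's effect in FOXA1-edited and in control cells was tested as an interaction. Interferon-stimulated genes were at a median log2 difference of -1.51, with 0 of 25 above 0 (camera adjusted p = 1.23e-24, and adjusted p = 0.013 with an estimated correlation), their medians being 0.95 with the drug in control cells and -0.48 in FOXA1-edited cells. Estrogen-repressed genes were at -1.72 with 0 of 13 above 0 (camera adjusted p = 1.95e-08, and adjusted p = 0.013 with an estimated correlation). Estrogen-induced genes were at 0.24 (camera adjusted p = 7.07e-12, and adjusted p = 0.0654 with an estimated correlation), or 0.85 with GC trends removed (camera adjusted p = 7.32e-22, adjusted p = 0.0133 with an estimated correlation). Members called adjusted over the list alone were 6 interferon-stimulated genes lower, 0 estrogen-repressed genes and 5 estrogen-induced genes higher. With GC trends removed they were 19 of 25 lower, 7 of 13 lower and 13 of 38 higher. Mesenchymal (-1.39), inflammatory (-1.14) and mitosis genes (0.37) were at camera adjusted p = 0.000705, 0.000705 and 0.00642, with 0 members called. They were at adjusted p = 0.0608, 0.118 and 0.154 with an estimated correlation. GC-corrected, their medians were -1.04, -0.46 and 0.35, at adjusted p = 0.0548, 0.276 and 0.141 with an estimated correlation. Over all genes edgeR called 0 genes for the interaction, with 464 at an unadjusted p under 0.05, DESeq2 called 10 and limma-voom 0. The GC-corrected fit called 5 genes. The drug effect was more positive in FOXA1-edited cells for CXCL12 at 2.70 (SE 0.31, GC-corrected edgeR adjusted p = 0.0441) and NPY1R at 2.51. It was more negative for the interferon-stimulated gene XAF1 (-2.93), DDX60 (-1.72) and PARP14 (-1.63). The count of 0 became 56 without FOXA1-edited replicate 2 and 1 without replicate 1. The GC-corrected count of 5 became 148 and 24 in the same order, and 0 without any of the other 8 libraries.

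Drug-treated control cells were compared directly with ESR1-edited cells. ESR1 RNA was 296 ± 40.3 CPM with the drug and 131 ± 11.9 with ESR1 edited (n = 2 each), a log2 difference of 1.17 (SE 0.32, edgeR adjusted p = 1). GREB1 stood at 9.84 ± 1.1 and 24.9 ± 6.5 CPM (log2 -1.34, SE 0.29, edgeR adjusted p = 1). GFRA1 measured 139 ± 3.32 and 243 ± 27.5 CPM, APOD 232 ± 40.5 and 246 ± 51.5, and IFIT1 269 ± 5.6 and 254 ± 55.3. By edgeR 0 genes were called, with 20 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Estrogen-induced genes (-0.11), DNA replication and E2F genes (-0.17), mitochondrially encoded genes (0.21), estrogen-repressed genes (0.16) and mitosis genes (-0.16) were at camera adjusted p = 0.00149, 0.000748, 0.000748, 0.0224 and 0.0224. They were at adjusted p = 0.38, 0.114, 0.38, 0.296 and 0.38 with an estimated correlation. Interferon-stimulated genes had a median difference of -0.06 (camera adjusted p = 0.638). A p past the threshold in neither direction does not show that drug and editing act alike.

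FOXA1-edited cells were compared directly with ESR1-edited cells, both untreated. DPP4, which encodes a cell-surface peptidase, was at 88.7 ± 23.2 CPM with FOXA1 edited and 4.53 ± 0.0525 with ESR1 edited (n = 2 each), 4.29 (SE 0.36, edgeR adjusted p = 0.00618). S100A8, S100A9, CLMP, GRAMD1B, MYPN and the kinase gene SGK1 were higher at 5.14, 5.26, 5.92, 4.97, 3.41 and 3.03. CSTA was lower, 1.02 ± 0.382 against 88.3 ± 29.1 CPM at -6.40 (SE 0.50, edgeR adjusted p = 0.00499). Also lower were LDLRAD4 (-6.39), PMP22 (-5.29), GLRA3 (-3.65), PPP1R3C (-3.51), the fibrillin gene FBN2 (-3.38) and the prolyl hydroxylase gene EGLN3 (-3.31). In all 22 genes were called, 10 higher and 12 lower, and 384 (176 and 208) with GC trends removed, including all 22. With the compared groups alone edgeR called 0 genes, and limma-voom with sample quality weights called 4. GREB1 was at 61 ± 5.28 and 24.9 ± 6.5 CPM, a log2 difference of 1.29 (SE 0.29, edgeR adjusted p = 0.168). Interferon-stimulated genes were higher with FOXA1 edited at 1.68 (camera adjusted p = 2.79e-15, and adjusted p = 0.021 with an estimated correlation), with 0 called over all genes and 20 of 25 adjusted over the list alone. Inflammatory genes were higher at 2.51 (camera adjusted p = 6.43e-10, and adjusted p = 0.021 with an estimated correlation), with 0 called over all genes and 7 of 12 adjusted over the list alone. Basal and myoepithelial genes were higher at 1.33 (camera adjusted p = 3.26e-07, and adjusted p = 0.021 with an estimated correlation), with CD44 at 1.95 the 1 of 17 called and 6 adjusted over the list alone. In the GC-corrected fit these 3 were at adjusted p = 0.0581, 0.0581 and 0.0932 with an estimated correlation, while 10, 3 and 3 members rose over all genes. Estrogen-induced genes (0.76), mitosis genes (-0.51), stress response genes (0.78) and p53 targets (0.56) were at camera adjusted p = 0.00869, 0.00229, 0.0048 and 0.0375. They were at adjusted p = 0.42, 0.101, 0.101 and 0.106 with an estimated correlation. GC-corrected, their medians were 0.33, -0.39, 0.44 and 0.25, and the estrogen-induced list no longer passed (camera adjusted p = 0.134). The luminal list was at 0.38 (camera adjusted p = 0.435), or -0.21 with GC trends removed (camera adjusted p = 0.0353, adjusted p = 0.123 with an estimated correlation). BCAS1 was lower at -2.80 (SE 0.33, edgeR adjusted p = 0.0268). The estrogen-repressed list stood at -0.64 (camera adjusted p = 0.00626, adjusted p = 0.101 with an estimated correlation), and with GC trends removed 5 of 13 fell and 1 rose over all genes. Mitochondrially encoded genes were at -0.86 (camera adjusted p = 1.69e-08, adjusted p = 0.101 with an estimated correlation), with 9 of 13 lower adjusted over the list alone with GC trends removed. The count of 22 became 0 and 1 without ESR1-edited replicates 2 and 1, 4 without either drug-treated FOXA1-edited library, and 5 without either drug-treated control library. It became 8 without control replicate 2, 273 without FOXA1-edited replicate 2 and 2884 without replicate 1. With GC correction, 384 became 86 and 70 without ESR1-edited replicates 1 and 2, 209 and 205 without drug-treated control 1 and 2, and 1578 and 845 without FOXA1-edited 1 and 2.

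Calls were compared across the 3 comparisons that share the control libraries. GREB1 was called lower with the drug, with ESR1 edited and with FOXA1 edited, and GFRA1 with the drug and with FOXA1 edited, where it measured 91.4 ± 13.2 CPM. In the GC-corrected fit 25 genes were higher and 19 lower both with the drug and with ESR1 edited, and 0 were opposite. Independent lists would share 0.0672 and 0.044. The drug and FOXA1 editing shared 21 higher and 29 lower with 2 opposite (1.08 and 0.82 for independent lists), and the 2 edited genes shared 16 higher and 17 lower with 1 opposite (0.806 and 0.443). These shared counts moved with single libraries: the 44 for the drug and ESR1 editing became 0 without control replicate 2 or either ESR1-edited library, 2 without control replicate 1 and 1 without either drug-treated control library. They became 23 without either drug-treated FOXA1-edited library, and 136 and 158 without FOXA1-edited replicates 1 and 2. With each library left out in turn, the 50 for the drug and FOXA1 editing ran from 1 to 167, and the 33 for ESR1 and FOXA1 editing from 0 to 96. Simulated unchanged groups against simulated controls common to the comparisons shared 0, 0.1 and 0 genes on average. Simulated counts were drawn independently for each gene, without deviations that genes of a real library share. They may therefore understate what shared controls alone can give. Their dispersions were pooled over all groups, with a biological coefficient of variation (spread between replicates relative to the mean) of 0.525, or 0.363 without FOXA1-edited replicate 2. With GC trends removed these were 0.355 and 0.255. The simulated spread of control libraries, and so the simulated covariances, may therefore also be too high. APOD, BCAS1, SELL, CRISP3 and ITGB6, each called higher with the drug and with ESR1 edited in the GC-corrected fit, stood with FOXA1 edited at 33.1, 17.5, 61.1, 9.33 and 122 CPM against 34.8, 31.6, 45.6, 13.2 and 86.3 in control cells. Log2 fold changes across 10785 genes correlated at r = 0.859 between the drug and ESR1 editing, against 0.501 for simulated unchanged groups, with a covariance of 0.188 against 0.177, or 0.178 against 0.0795 with GC trends removed. For the drug and FOXA1 editing r was 0.327 against 0.502, with a covariance of 0.192 against 0.177, or 0.165 against 0.0796 with GC trends removed. For ESR1 and FOXA1 editing r was 0.423 against 0.499, with a covariance of 0.246 against 0.176, or 0.202 against 0.0799 with GC trends removed. The 2 control libraries were not split between the comparisons, and part of the excess may come from the shared controls. The drug's effects in control and in FOXA1-edited cells, which share 0 libraries, correlated at r = 0.0633 across genes, or 0.124 with GC trends removed. Their calls could not overlap, since 0 genes were called in FOXA1-edited cells in either fit, and in the GC-corrected fit without FOXA1-edited replicate 1 or 2, with 152 and 269 called there, 8 and 25 genes were called in both in the same direction.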

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

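All the tests of explanations in this part were chosen after the result each measures was seen, and the GC-corrected fit on which most rest was too. For 2 of them, the level of drug-lowered genes in FOXA1-edited replicate 2 and the estrogen-induced list under the drug, the reading was also changed after the value was seen, from in favor of the explanation to undecided, for the reasons given with each.

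The drug effect differed between FOXA1-edited and control cells for 5 genes in the GC-corrected edgeR test of the interaction, each at an adjusted p of 0.0441: NPY1R by log2 2.51 (SE 0.266; -3.38 in control and -0.863 in FOXA1-edited cells), CXCL12 by 2.70 (SE 0.315; -2.47 and 0.229), XAF1 by -2.93 (SE 0.328; 2.21 and -0.72), DDX60 by -1.72 (SE 0.201; 1.32 and -0.398) and PARP14 by -1.63 (SE 0.193; 1.32 and -0.312), a count that became 24 or 148 without untreated FOXA1-edited replicate 1 or 2 and 0 without any of the other 8 libraries. As lists, estrogen-induced genes had a median of -1.25 with the drug in control and -0.717 in FOXA1-edited cells, against -1.22 and -0.184 GC-corrected. The median of -0.184 rests on a correction chosen after the data were seen. In FOXA1-edited cells the GC-corrected list was still lower than other genes, with 13 of 38 above 0 (camera adjusted p = 0.000402, but adjusted p = 0.216 with an estimated correlation). Interferon-stimulated genes had medians of 0.953 and -0.485, or 0.918 and -0.346 GC-corrected, opposite in sign (the negative medians at adjusted p = 0.225 and 0.216 with an estimated correlation). A single library is argued against, since in the GC-corrected fit both interactions held without either untreated FOXA1-edited library (highest camera adjusted p 2.97e-12 at the preset correlation; medians 0.957 and 1.12, and -1.32 and -1.24, without replicates 1 and 2), and so are GC trends as the whole cause for interferon-stimulated genes, with 89.4% of the interaction median left after correction, while the estrogen-induced interaction grew from 0.242 to 0.851 and passed only then with an estimated correlation (adjusted p = 0.0654 and 0.0133), so its size depends on the correction. With the drug in both arms, interferon-stimulated genes had a GC-corrected median 0.721 higher in FOXA1-edited cells (camera adjusted p = 4.29e-13, but adjusted p = 0.0528 with an estimated correlation), and the 7 of 25 called higher with 0 lower argue against a common level under the drug for those genes, while for estrogen-induced genes the median was 0.00795, but CXCL12 and MYC were called higher and RET and ELOVL2 lower, so a median near 0 over members going both ways leaves a shared floor of estrogen receptor output open. A biological explanation from the design, that for estrogen-induced genes FOXA1 editing already removes part of what the drug removes, may also apply. In untreated FOXA1-edited cells that list already stood at a GC-corrected median of -1.07 against control, as this explanation would give. That value and the drug effect in control cells rest on the same control libraries, and the explanation was not tested by itself.

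The 2 untreated FOXA1-edited libraries differed from each other (r = 0.81 across genes), with GAPDH at 1150 CPM in replicate 2 against 39.5 to 167 in the other 9 libraries. A GC trend explained 67.3% of the variance of replicate 2's deviation and may account for most of it, but with trends removed the libraries correlated at 0.907 against at least 0.956 in the other 4 replicate pairs, so it does not account for all. Deviations are measured from the mean of all libraries, so they do not tell whether replicate 2 or the other libraries misstate GC-rich transcripts. Cells without FOXA1 editing are argued against: of 507 genes called for FOXA1 editing under the drug, 96.1% moved the same way in replicate 2 and 95.7% in replicate 1. Drug-treated cells as the source of replicate 2 cannot be told apart by the 37 genes the drug lowered, which stood at a median log2 of 0.444 above the drug-treated FOXA1-edited libraries in replicate 2 (quartiles 0.0741 and 1.29) and 0.495 in replicate 1. In replicate 2, 31 of the 37 stood above the drug-treated libraries. GREB1 was at 64.7 CPM there against 11.5 and 8.79 (GC-corrected 33.7 against 9.47 and 9.45), as its label says. The median did not pass the bound of 0.5 that would exclude the explanation. Replicate 1 did not pass it either, so the bound cannot tell an untreated from a drug-treated library here. Drug treatment of replicate 2 therefore stays open, as does the kit, which the labels assign to no library.

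Interferon-stimulated genes rose against the untreated controls with the drug, with ESR1 edited and with FOXA1 edited. In GC-corrected values both libraries stood above both controls for 23 of 25 genes in each comparison, where random order gives 4.17 on average. Genes of this list move together between libraries (GC-corrected estimated correlation 0.279 with FOXA1 edited). The 23 are therefore not independent counts and do not measure how unlikely the rise is. GC trends are argued against, since at least 96.3% of the list's median remained in each comparison, and so is 1 library alone, since the highest camera adjusted p with each of 10 libraries left out was 5.95e-11 at the preset correlation. The guide preparation is argued against for the drug comparison, where both arms carried the same guide and the GC-corrected median was 0.918. For the knockouts, where the median with FOXA1 edited was 2.77, it cannot be told apart from the edit, because each target had its own guide and the control guide was in no knockout library. The same 2 control libraries stand in all 3 comparisons, so a lower level in those cultures may account for the shared part, which a second control set would test.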

How the results depend on the processing

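Settings added after the data were seen were the GC corrections and quality weights, and the others were fixed before. Counts of called genes follow in the order drug in control cells, ESR1 edited, FOXA1 edited, drug in FOXA1-edited cells, FOXA1 edited under the drug, interaction, drug against ESR1 edited, and FOXA1 against ESR1 edited. As reported they were 2, 1, 119, 0, 49, 0, 0 and 22. Genes shared between comparisons were counted for the drug with ESR1 edited, the drug with FOXA1 edited, ESR1 with FOXA1 edited, and the drug in FOXA1-edited cells with the drug in control cells and with ESR1 edited, 1, 2, 1, 0 and 0 as reported. With the setting DESeq2 size factors in edgeR they were 2, 1, 111, 0, 43, 0, 0 and 22, with 1, 2, 1, 0 and 0 genes shared. With the setting DESeq2 they were 79, 49, 1623, 25, 424, 10, 0 and 1084, with 40, 46, 31, 3 and 3 genes shared. With the setting limma-voom they were 2, 2, 103, 0, 54, 0, 0 and 18, with 2, 2, 2, 0 and 0 genes shared. With the setting no filter on low counts they were 30, 21, 2240, 770, 263, 173, 0 and 1820. With the setting stricter filter they were 2, 1, 151, 0, 57, 0, 0 and 44. With the setting only the groups compared they were 0, 12, 0, 0, 544, 0, 0 and 0. With the setting replicate block they were 2, 0, 10, 0, 24, 0, 0 and 6, with 0, 1, 0, 0 and 0 genes shared. With the setting adjusted p under 0.01 they were 1, 0, 6, 0, 7, 0, 0 and 3. With the setting adjusted p under 0.05 and at least 2-fold they were 2, 1, 119, 0, 49, 0, 0 and 22, with 1, 2, 1, 0 and 0 genes shared. With the setting GC correction they were 76, 49, 841, 0, 507, 5, 0 and 384, with 44, 50, 33, 0 and 0 genes shared. With the setting GC and length correction they were 99, 58, 882, 0, 552, 3, 0 and 393, with 57, 64, 38, 0 and 0 genes shared. With the setting GC correction, replicate block they were 58, 38, 787, 0, 473, 0, 0 and 344, with 35, 39, 27, 0 and 0 genes shared. With the setting limma-voom with sample quality weights they were 37, 16, 5, 0, 591, 0, 0 and 4, with 15, 1, 1, 0 and 0 genes shared.

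With each library left out in turn, where the remaining library of a group is assumed to vary like the other groups, the 8 counts ran from 0 to 18, 0 to 7, 2 to 4470, 0 to 588, 0 to 340, 0 to 56, 0 to 0 and 0 to 2884, and the 5 shared counts from 0 to 7, 0 to 11, 0 to 3, 0 to 3 and 0 to 2. With GC trends removed as well, the counts were 11, 2, 233, 0, 350, 0, 0 and 270 without control replicate 1 (shared 2, 7, 2, 0 and 0). The counts were 9, 0, 165, 0, 340, 0, 0 and 274 without control replicate 2 (shared 0, 6, 0, 0 and 0). They were 1, 6, 460, 0, 113, 0, 0 and 209 without drug-treated control replicate 1 (shared 1, 1, 5, 0 and 0). The counts were 1, 9, 464, 0, 97, 0, 0 and 205 without drug-treated control replicate 2 (shared 1, 1, 7, 0 and 0). They were 28, 0, 513, 0, 315, 0, 0 and 86 without ESR1-edited replicate 1 (shared 0, 19, 0, 0 and 0). The counts were 28, 0, 515, 0, 309, 0, 0 and 70 without ESR1-edited replicate 2 (shared 0, 19, 0, 0 and 0). They were 277, 150, 2480, 152, 1035, 24, 0 and 1578 without FOXA1-edited replicate 1 (shared 136, 167, 90, 8 and 6). The counts were 318, 175, 1223, 269, 1110, 148, 0 and 845 without FOXA1-edited replicate 2 (shared 158, 151, 96, 25 and 14). They were 39, 24, 636, 0, 203, 0, 0 and 273 without drug-treated FOXA1-edited replicate 1 (shared 23, 26, 18, 0 and 0). The counts were 34, 24, 626, 0, 143, 0, 0 and 270 without drug-treated FOXA1-edited replicate 2 (shared 23, 23, 18, 0 and 0). The highest counts came without FOXA1-edited replicate 1 or 2, except for the drug against ESR1 edited, where 0 genes were called throughout by edgeR (20 at an unadjusted p under 0.05 as reported), DESeq2 and limma-voom. Fewer calls at an adjusted p under 0.01 follow from the threshold itself, and the cause of the other changes was not tested. Over 264 alternative counts, 106 stayed within 1.5 times and 158 moved, and over 145 shared counts 58 stayed and 87 moved. Of 26938 values for named genes, 23862 kept direction and side of the threshold, 692 lost the call, 2381 gained it and 3 reversed, and 544 uncalled values changed sign: reversed were FOXM1 in C8, the code for FOXA1 against ESR1 edited (-0.889 with GC correction without FOXA1-edited replicate 1), and, with GC correction without FOXA1-edited replicate 2, TFF1 with FOXA1 edited (-3.85) and in the interaction (3.69). Of 3808 values for lists, 3494 were the same, 181 lost the call, 130 gained it and 3 reversed, and 178 uncalled values changed sign: reversed were mitochondrially encoded genes in the interaction (adjusted p = 0.01 with GC and length correction and 0.0459 without FOXA1-edited replicate 2) and luminal genes for the drug in FOXA1-edited cells (0.785 without FOXA1-edited replicate 2), and the cause was not tested. Over the left-out libraries the adjusted p of these lists ran from 0.0459 to 0.961 and from 0.00117 to 0.785. Deviations of libraries with the same number correlated across genes at 0.329 to 0.891 in all 6 pairs of the 4 groups besides untreated FOXA1-edited cells, as a shared effect of the number would give, and at -0.854 to -0.417 in the 4 pairs with those cells. With GC trends removed these ran from 0.0228 to 0.769 and from -0.614 to -0.0512, and since not every pair was above 0.1 the block was not taken as a pairing. Exchanging the numbers of the 2 untreated FOXA1-edited libraries would turn the sign in those 4 pairs. An effect shared by all groups, with that pair in reverse order, therefore stays open. A block with that order was not fitted. Depth limits low genes: a group at 0 counts allows up to 3.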

Other observations

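The test of the gene cluster on chromosome 1 and the tests of chromosome ends were chosen before their results were seen, after S100A8, S100A9 and IVL had been seen to rise. S100A8 and S100A9 lie in a cluster of epidermal differentiation genes on chromosome 1 (151982915 to 153632039, from S100A10 to S100A1), and the hypothesis that the cluster rose as a block was tested on its 17 other measured genes. With GC trends removed their median log2 change was 0.849 with FOXA1 edited (12 of 17 above 0, 6 called higher and 0 lower, p = 0.00533 by camera with an estimated correlation) and 1.08 with FOXA1 edited under the drug (14 above 0, 4 called higher and 0 lower, p = 0.00224), which is consistent with a rise of the cluster. TCHHL1 was at 3.59 and 2.68 and S100A14 at 1.14 and 1.08 in these comparisons. S100A10 was at 0.42 and 0.43 and not called, so the rise did not take in every gene. The filter can keep a gene expressed in only 1 group, so some members may have entered only through FOXA1-edited libraries where they are high. Such selection would raise the medians and lower the p-values. Epidermal genes outside the cluster were not tested beside it. The test therefore cannot tell a rise of the cluster as a block from separate rises of epidermal genes.

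Loss of the chromosome end beyond a Cas9 site would lower the genes beyond it. Beyond ESR1 on chromosome 6, 58 genes had a GC-corrected median of 0.0497 with ESR1 edited, where all genes had 0.00682 (p = 0.752 by camera with an estimated correlation). These genes thus showed no drop, but a p that does not pass cannot exclude loss in a share of cells. Beyond FOXA1 on chromosome 14, 436 genes had medians of -0.0967 with FOXA1 edited and -0.0531 under the drug, where all genes had 0.0614 and 0.0503. Camera with an estimated correlation gave p = 0.0143 and p = 0.0145, and with the preset correlation p = 0.0476 and p = 0.109. Neither median reached the bound of -0.1 set beforehand, but the first came close and both p-values with an estimated correlation were under 0.05. On the centromeric side of FOXA1, 146 genes had medians of 0.112 and 0.00486 (p = 0.75 and p = 0.983 by camera with an estimated correlation). Only the side beyond the cut was thus lower by camera, and the shift was small. The bound was measured from 0 and left out the shift of all genes, so the test cannot decide, and loss in a share of cells stays open.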
